A study of Mus musculus with 6 samples.

How the data were processed

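RNA sequencing libraries of mouse bone marrow monocytes were compared at day 0 and day 5 of RANKL exposure, with 3 libraries on each day. Per the labels' protocols, poly(A) RNA was selected from total RNA, libraries were made with a dUTP method that keeps the strand, and they were sequenced as read pairs on an Illumina NovaSeq instrument. The submitters' processing notes name fastp, HISAT2, StringTie and edgeR, without versions, and the build GRCh38, which is a human assembly. The gene identifiers of the deposited table are mouse. Of 28795 genes, 28722 (99.7%) are in the mouse annotation GENCODE M21 for build GRCm38, all 28722 on the same chromosome and 90.4% with the same start and end, so coordinates are given as in the table, with GRCm38 named as the build they match. Whether reads were counted by strand, and how reads shared by overlapping genes were assigned, is not given in the sources used here.

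Per its headers, the deposit holds counts per gene and FPKM values for each of the 6 libraries. The counts are whole numbers that the authors deposited without normalization. The FPKM values were scaled by the authors for gene length and library depth before they were deposited. The analysis planned before the data were examined was a limma fit to log2(FPKM + 1), with the count test to replace it if raw counts were present. Counts taken as raw were present, so edgeR's quasi-likelihood test on the counts is the main test, and the planned limma fit became an alternative.

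Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested, 11908 in all. Counts were scaled by TMM in edgeR 4.0.16 (R 4.3.3, limma 3.58.1, DESeq2 1.42.0). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 difference of at least 1 in size. The standard error was taken from the log2 difference and the quasi-likelihood F statistic. For a gene with a count of 0 on 1 day, a floor of 3 counts over that day was used and the fold is given as a lower bound. The common biological coefficient of variation was 0.117. The smallest chi-square per degree of freedom between libraries of 1 day was 22.9, so no pair differed as little as sampling noise. The library day 0 replicate 1 had 4.09% of its counts in an 18S rRNA-related gene, against 0.158% to 0.507% in the other libraries.

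Named genes followed a rule fixed before the data were examined. They are 16 genes of the study's question, the 8 largest rises and 8 largest falls on the log2(FPKM + 1) scale among called genes whose days did not overlap, and from each of 30 fixed lists up to 3 called members with the largest difference, or the most abundant member where none was called. Some genes that this rule names are not reported here. Symbols were matched without regard to case, and a member without a match was looked up through gene synonyms. Where a symbol was repeated, the most abundant entry was used. Lists share members, such as Atp6v0d2, which is in 3 of them. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. For each of the 30 lists the number of members called was the same when p-values were adjusted over the list alone. With the preset, 16 of the 29 lists that could be tested were called, and 2 with the estimated correlation, the osteoclast list and the complement and phagocytic receptor list. The preset p-values are therefore weak evidence taken alone. Splits of the 6 libraries that mixed the days called 9 to 16 lists with the preset. Their groups held the days in unequal numbers, so part of the day difference remained between them. These splits cannot show how often the preset calls a list without a day difference. Lists named as chosen after the values were seen were fitted without the filter on low values, unless stated. The genes shared by macrophages and osteoclasts are the exception, and their values come from the main fit with the filter.

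Counts for 11908 genes were simulated from the day 0 means, the library sizes and edgeR's own gene dispersions. On them edgeR recovered 99 of 100 genes changed by a log2 of 1.5 and 100 of 100 changed by 2, with 6 false calls. No other genes were changed there, while 6608 had an adjusted p under 0.05 in the data. The simulation therefore does not show error rates when that many genes differ. Alternatives were other pseudocounts, filters, scalings and thresholds, limma without trend or robust, each replicate left out, and a replicate block. DESeq2, filterByExpr, library totals without TMM and robust edgeR were added after the data were examined, as was a count of called list members without the library richest in 18S-related reads. Figures were drawn with matplotlib 3.10.9.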

Results

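Gene expression was measured by RNA sequencing in mouse bone marrow monocytes, macrophage and osteoclast precursors that were grown in M-CSF (50 ng/ml), the cytokine that keeps these cells alive. RANKL, the cytokine that drives their differentiation into bone-resorbing osteoclasts, was given at 50 ng/ml. There were 3 libraries at day 0 and 3 at day 5 of RANKL exposure. The series set out to follow Vsig4, a complement receptor of the immunoglobulin superfamily, during osteoclast formation, and its title also names Nrf2 and reactive oxygen species. The counts over the genes of the deposited table summed to 64616609, 71849263 and 82721513 per library at day 0 and to 73234377, 70888492 and 71551214 at day 5. No culture kept for 5 days in M-CSF without RANKL was analysed here, so every difference below is between day 5 with RANKL and day 0, and holds the effects of RANKL and of time in culture together. The treatment label of the day 0 libraries also reads RANKL, and the time label was used to group them. Nothing in the labels says that the 3 libraries of a day came from separate cultures or animals, so the p-values measure only the spread between these libraries. Values are means ± SD of CPM (counts scaled to a library total of 1e6 after TMM normalization) with n = 3 per day unless stated, log2 differences are day 5 minus day 0 with their standard error (SE), and adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

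Between day 0 and day 5 22 of 25 osteoclast genes and 14 of 18 proton pump subunits rose, and 18 of 25 complement and phagocytic receptors fell. Of 11908 genes tested, 695 were higher and 770 lower at day 5 with an adjusted p under 0.05 and a log2 difference of at least 1 in size, 1465 in all. The 3 libraries of 1 day all lay above the 3 of the other day for 1461 of these genes. Over all tested genes this was so for 63.3%, where chance gives 10%. Without the size threshold the test called 6608 genes, 3173 higher and 3435 lower. Replicates of a day correlated across genes at r of 0.988 to 0.990, against 0.894 to 0.911 between days. The count of 1465 depends on the filter for low values and on the test, and ranged from 839 to 2366 under other filters and tests at the same thresholds.

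**Figure D1:**
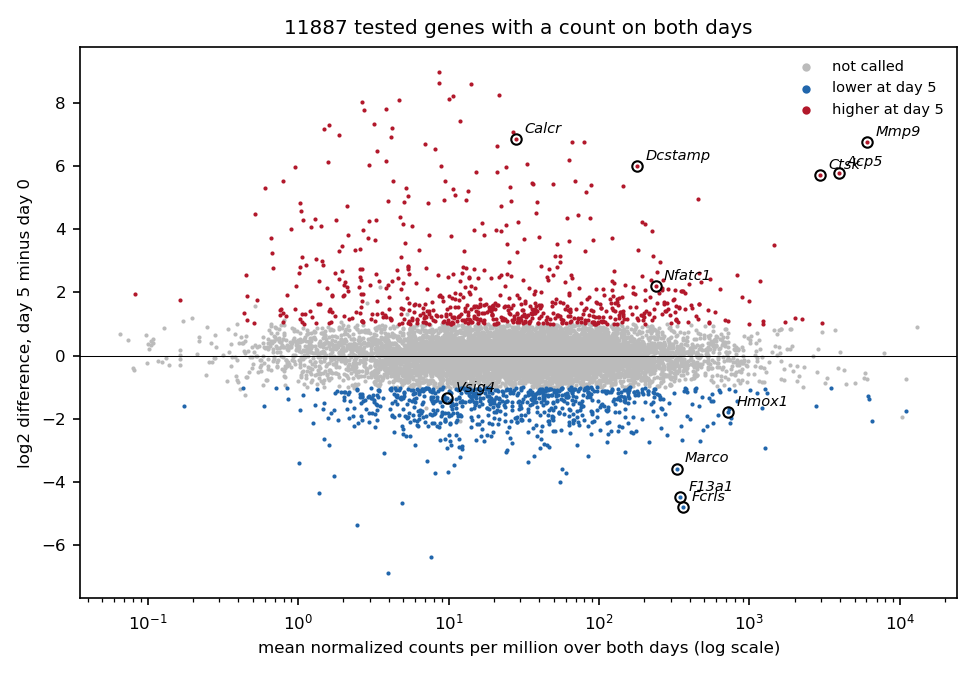
Log2 difference (day 5 minus day 0, vertical axis) against the mean CPM over both days (horizontal log axis) for the 11887 tested genes with a count on both days; 21 genes with a count on 1 day only are left out. Red points are genes called higher and blue points genes called lower at day 5, and the circled genes show Mmp9, Acp5 and Ctsk among the abundant transcripts that rose, and Fcrls, F13a1 and Marco among those that fell.

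Vsig4, the gene the series is about, fell 2.52-fold. It had 14.1 ± 0.813 CPM at day 0 and 5.57 ± 0.200 CPM at day 5, a log2 difference of -1.34 ± 0.12 (SE, adjusted p = 3.31e-06). The gene (ENSMUSG00000044206, chromosome X, 96247203 to 96293438 on the minus strand, in coordinates that match mouse build GRCm38) had 894, 1034 and 1059 counts in the day 0 libraries and 391, 410 and 415 at day 5. Each day 0 library lay above each day 5 library, and the exact two-sided permutation test of 3 against 3 libraries gave p = 0.1, the smallest this design allows. Nfe2l2, which encodes the transcription factor Nrf2 (chromosome 2, 75675513 to 75704641), went from 211 ± 10.4 to 127 ± 3.36 CPM, a log2 difference of -0.73 ± 0.07 (adjusted p = 3.27e-06) that did not reach the size threshold. Hmox1, encoding the haem-degrading enzyme heme oxygenase 1, fell 3.46-fold from 1119 ± 35.3 to 323 ± 43.6 CPM (adjusted p = 5.13e-08). Keap1, whose product binds Nrf2 and targets it for degradation, had a log2 difference of -0.52 ± 0.08 (adjusted p = 1.49e-04), and Nqo1, a quinone reductase, one of -0.56 ± 0.13 (adjusted p = 0.00358). Both differences lay beyond the replicate spread and below the size threshold.

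Osteoclast genes had the highest median difference of the fixed lists. Of the 25 tested members of the list of osteoclast resorption and differentiation genes, 22 rose, 0 fell and 3 were not called, with a median log2 difference of 3.95. The count adjusted over the list alone was also 22. Mmp9, a collagen-degrading protease (chromosome 2, 164940780 to 164955850), rose 108-fold from 112 ± 37.8 to 12069 ± 1368 CPM (log2 6.76 ± 0.27, adjusted p = 4.81e-09). Acp5, the tartrate-resistant acid phosphatase used to stain osteoclasts (chromosome 9, 22126727 to 22135711), rose 55.5-fold from 139 ± 31.9 to 7733 ± 493 CPM. Ctsk, the protease that cleaves bone collagen (chromosome 3, 95499256 to 95509362), rose 52.8-fold from 110 ± 12.4 to 5814 ± 185 CPM. Calcr, the calcitonin receptor, rose 116-fold from 0.476 ± 0.182 to 56.0 ± 2.71 CPM. Oscar, a collagen receptor of osteoclasts, rose 108-fold from 1.20 ± 0.265 to 130 ± 2.27 CPM. The list passed the camera set test with its preset correlation (adjusted p = 2.00e-72) and with an estimated correlation (adjusted p = 0.0324). Scin, an actin-severing protein, rose 73.3-fold, and the unnamed gene model 4833415N18Rik rose 101-fold from 0.420 ± 0.392 to 41.4 ± 2.91 CPM.

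**Figure D2:**
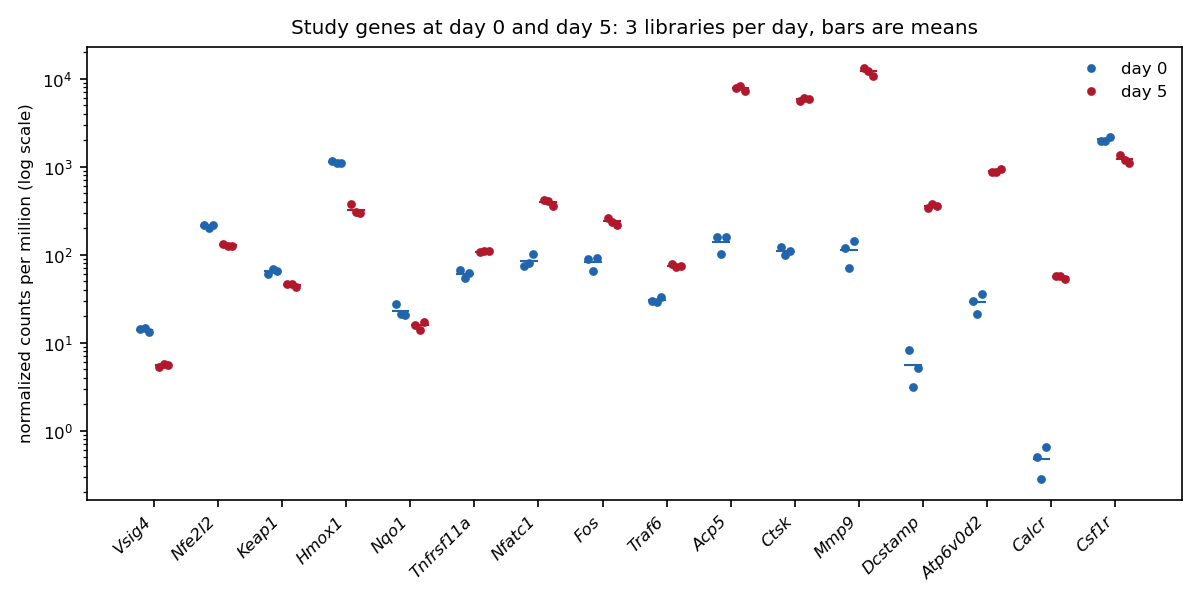
CPM (vertical log axis) of 16 genes chosen for their place in the study's question, with 1 point per library, day 0 in blue and day 5 in red, and a bar at each mean of 3 libraries. Vsig4 went from 14.1 to 5.57 CPM and Hmox1 from 1119 to 323 CPM, while Mmp9, Acp5, Ctsk, Dcstamp, Atp6v0d2 and Calcr rose between 30.8-fold and 116-fold.

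Of 18 subunits of the vacuolar ATPase, which acidifies lysosomes and the resorption pit, 14 rose and 1 fell, with a median log2 difference of 1.36 and 14 and 1 when adjusted over the list alone. Atp6v0d2, the osteoclast subunit, rose 30.8-fold from 28.8 ± 7.16 to 887 ± 39.8 CPM, Atp6v1b2 rose 5.10-fold from 385 ± 23.9 to 1961 ± 64.9 CPM, and Tcirg1 rose 4.32-fold from 241 ± 7.66 to 1040 ± 77.6 CPM. Camera gave adjusted p = 1.15e-18 for this list and adjusted p = 0.0553 with an estimated correlation. Of 16 cell fusion genes 5 rose and 2 fell. Dcstamp and Ocstamp, membrane proteins required for osteoclast fusion, rose 64.5-fold (5.52 ± 2.63 to 353 ± 18.1 CPM) and 36.6-fold (4.37 ± 1.55 to 161 ± 13.9 CPM). Camera gave the fusion list adjusted p = 8.88e-06, and adjusted p = 0.183 with an estimated correlation. Of 24 podosome and cytoskeleton genes 7 rose and 0 fell. Among them were Itgb3, a subunit of the vitronectin receptor, 15.5-fold from 27.4 ± 4.08 to 425 ± 27.9 CPM, Pstpip1, an actin-linked adaptor, 5.68-fold, and Dock5, a Rac activator, 5.27-fold. The median of the podosome list was -0.05 while its mean was 0.57 and camera pointed up (adjusted p = 1.09e-04, and adjusted p = 0.388 with an estimated correlation).

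Signalling genes downstream of RANK moved in both directions. Of 35 components, 6 rose and 3 fell, with a median log2 difference of 0.20, and the list narrowly missed the threshold (camera unadjusted p = 0.0293, and adjusted p = 0.541 with an estimated correlation). Nfatc1, the transcription factor at the centre of osteoclast differentiation (chromosome 18, 80606205 to 80713071), rose 4.59-fold from 85.3 ± 13.6 to 391 ± 33.7 CPM. Nfkbia, an inhibitor of NF-kB, rose 3.62-fold, Fos, an AP-1 subunit, 2.92-fold, and Traf6, the adaptor that RANK recruits, 2.44-fold. Trem2, a receptor that signals through an ITAM adaptor, fell 3.37-fold from 355 ± 44.4 to 105 ± 8.04 CPM. The receptors themselves stayed under the size threshold. Tnfrsf11a, which encodes RANK, had a log2 difference of 0.83 ± 0.08 (60.7 ± 5.90 to 108 ± 1.88 CPM), and Csf1r, the M-CSF receptor, one of -0.74 ± 0.09 (2038 ± 107 to 1222 ± 130 CPM). Of 15 repressors of osteoclast differentiation, 5 fell and 1 rose, with a median of -0.75. Id1 fell 4.21-fold and Irf8 3.97-fold, both transcriptional regulators that restrain the osteoclast programme. Camera gave this list adjusted p = 0.00316, and adjusted p = 0.233 with an estimated correlation. Among 18 stress and immediate early genes, 4 rose and 1 fell (camera adjusted p = 0.548). Fos and Egr1 rose, the latter 2.17-fold, and Atf3 fell 4.44-fold from 76.1 ± 0.344 to 17.1 ± 1.52 CPM.

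Oxidant defence genes fell in part. Of 27 Nrf2 target genes 5 fell and 0 rose, with a median log2 difference of -0.54 and the same counts when adjusted over the list alone. Besides Hmox1 these included Mgst1, a membrane-bound glutathione transferase, 3.79-fold lower (99.5 ± 15.0 to 26.2 ± 1.84 CPM), and Cat, encoding catalase, 2.52-fold lower (766 ± 20.4 to 304 ± 28.9 CPM). Camera gave the list adjusted p = 6.23e-04, and adjusted p = 0.461 with an estimated correlation. The fixed stromal and osteoblast list had a median of -0.61 over the same days, and which cells carried the fall of the Nrf2 targets was not tested. Of 14 regulators of the Nrf2 pathway 1 fell, Trim21, an E3 ubiquitin ligase, 2.69-fold, and the list was not called (camera adjusted p = 0.342). Of 9 tested genes of reactive oxygen species production, 2 fell and 1 rose (camera adjusted p = 0.564). Ncf1 and Cybb, subunits of the phagocyte NADPH oxidase, fell 3.73-fold (383 ± 17.9 to 103 ± 14.7 CPM) and 3.17-fold (393 ± 40.6 to 124 ± 18.7 CPM), and Rac2, the small GTPase that activates the oxidase, rose 3.36-fold (142 ± 2.80 to 478 ± 45.1 CPM). Of 17 antioxidant enzymes outside the Nrf2 list 2 fell, Sod3, the extracellular superoxide dismutase, 2.79-fold, and Glrx, a glutaredoxin, 2.18-fold. The median of that list was 0.18, its mean -0.13 and its set test not called (camera adjusted p = 0.586). The log2 difference of Glrx was -0.99, under the size threshold, in limma on log2(FPKM + 1).

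Of 40 nuclear-encoded oxidative phosphorylation subunits 10 rose and 0 fell, with a median log2 difference of 0.76 (camera adjusted p = 1.68e-12, and adjusted p = 0.322 with an estimated correlation). Uqcrfs1 and Uqcrc2, subunits of complex III, rose 2.82-fold and 2.64-fold, and Sdha, of complex II, rose 2.37-fold from 262 ± 10.7 to 620 ± 16.9 CPM. Of 14 genes of mitochondrial biogenesis and the citrate cycle 5 rose and 0 fell, with a median of 0.89 (camera adjusted p = 1.59e-08, and adjusted p = 0.122 with an estimated correlation). Ppargc1b, a coactivator of mitochondrial biogenesis, rose 14.0-fold from 2.28 ± 0.374 to 32.2 ± 3.39 CPM, and Mdh2, the mitochondrial malate dehydrogenase, rose 3.08-fold. Of the 13 transcripts encoded in the mitochondrial genome 7 rose and 0 fell, with a median of 1.03 (camera adjusted p = 1.15e-07, and adjusted p = 0.322 with an estimated correlation). They included mt-Nd1, 1232 ± 109 to 2793 ± 186 CPM, mt-Nd5 and mt-Nd4l. All genes on the mitochondrial chromosome, not only these 13, together took 2.02% ± 0.110 of all counts at day 0 and 4.04% ± 0.303 at day 5. Under quantile normalization the log2 differences of mt-Nd1, mt-Nd5 and mt-Nd4l were 0.68, 0.93 and 0.97, below the size threshold, and mt-Nd4l overlaps mt-Nd4, so its counts are uncertain.

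Macrophage genes fell. Of 25 complement and phagocytic receptors 18 fell and 1 rose, with a median log2 difference of -1.84, and the list passed camera with the preset (adjusted p = 5.04e-23) and the estimated correlation (adjusted p = 0.0324). Marco, a scavenger receptor for bacteria, fell 11.9-fold from 605 ± 46.0 to 50.7 ± 8.81 CPM, Fcgr1, the high-affinity IgG receptor, 9.05-fold, and Stab1, a scavenger receptor, 7.59-fold. Of 19 macrophage identity genes 14 fell and 0 rose, with a median of -1.45 (camera adjusted p = 3.00e-16, and adjusted p = 0.0553 with an estimated correlation). Siglec1, a sialic acid receptor, fell 8.24-fold, and Cx3cr1, the fractalkine receptor, 6.61-fold. Of 23 interferon-stimulated genes 18 fell and 0 rose, with a median of -1.43 (camera adjusted p = 1.28e-11, and adjusted p = 0.0517 with an estimated correlation), with Oasl2 5.37-fold, Ifit3 4.21-fold and Bst2 3.63-fold lower. Ifit3 has a near-identical neighbouring copy and Cx3cr1 overlaps another expressed gene, so their counts are uncertain. By difference in log2(FPKM + 1), the largest falls in the data set included Fcrls, an Fc receptor-like scavenger receptor, 27.7-fold from 697 ± 91.9 to 25.1 ± 0.453 CPM, F13a1, the A chain of coagulation factor XIII, 22.3-fold from 664 ± 65.1 to 29.8 ± 2.07 CPM, Hpgd, a prostaglandin-degrading enzyme, from 112 ± 9.19 to 8.61 ± 0.753 CPM, and Ms4a4a, a membrane protein of macrophages, 12.8-fold. Over the same 5 days the summed CPM of 12 abundant stromal transcripts, a list chosen after the values were seen, went from 53361 ± 7504 to 30769 ± 1479. Of the 12, 2 were called lower. Fn1 (13476 ± 2995 to 8190.5 ± 739 CPM) and Thbs1 (8561 ± 1015 to 3618 ± 82.7 CPM) were the most abundant at day 0. Which cells carried these transcripts was not tested.

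Cytokine, antigen presentation and lysosomal genes were lower for part of their members. Of 14 tested inflammatory cytokines and chemokines 8 fell and 1 rose, with a median log2 difference of -1.04 (camera adjusted p = 0.0343, and adjusted p = 0.322 with an estimated correlation). The chemokines Ccl6 and Ccl3 fell 5.54-fold and 4.34-fold, and Ccl9 rose 3.04-fold from 202 ± 43.1 to 615 ± 18.2 CPM. Of 8 tested genes of MHC class II presentation 3 fell and 0 rose (camera adjusted p = 0.0861). These were Cd40, a costimulatory receptor, 3.67-fold, H2-DMa, a peptide-loading subunit, 3.56-fold, and Ctss, an invariant-chain protease, 2.17-fold lower. H2-DMa overlaps a more abundant gene, so its counts are uncertain. Of 27 lysosomal proteases and membrane proteins 7 fell and 1 rose (camera adjusted p = 0.0766). Ctsd, the aspartic protease cathepsin D, fell 2.57-fold from 8963 ± 438 to 3481 ± 265 CPM, Man2b1, a mannosidase, 2.71-fold, and Lipa, the acid lipase, 2.69-fold.

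**Figure D3:**
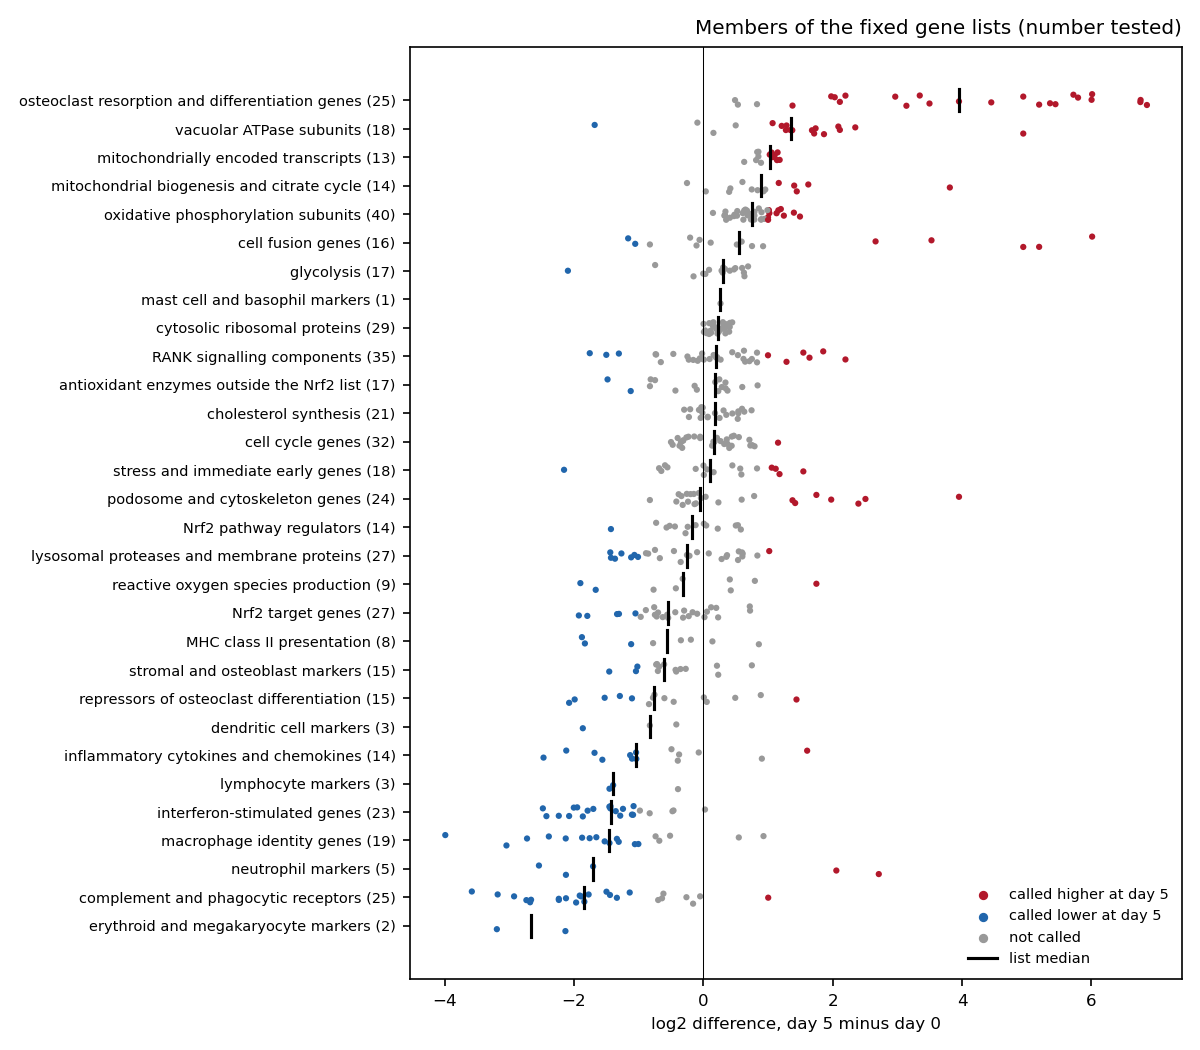
Log2 difference (day 5 minus day 0, horizontal axis) of the tested members of 30 gene lists fixed before the data were examined, with 1 point per gene, red for called higher, blue for called lower and grey for not called, and a black bar at each list's median. The osteoclast list has a median of 3.95 and the list of complement and phagocytic receptors one of -1.84, while ribosomal proteins lie close to 0 with a median of 0.22.

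Growth and housekeeping lists held few called genes. Of 32 cell cycle genes 1 rose, Bub1, a mitotic checkpoint kinase, 2.23-fold (camera adjusted p = 0.361). Its log2 difference was 0.96, under the size threshold, without replicate 3 of day 5, and 0.97 under quantile normalization. Of 17 glycolysis genes 1 fell, Hk3, a hexokinase of myeloid cells, 4.26-fold from 189 ± 2.86 to 44.2 ± 4.65 CPM (camera adjusted p = 0.347). Of 21 cholesterol synthesis genes (camera adjusted p = 0.134) and 29 cytosolic ribosomal proteins (camera adjusted p = 0.0848), edgeR called 0 at the size threshold, as did DESeq2 and limma. At an unadjusted p under 0.05 edgeR had 14 and 17 of them. Their most abundant members, Srebf2 and Rplp0, had log2 differences of 0.07 ± 0.07 and 0.22 ± 0.10.

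Markers of other cell types were also present. Of 15 tested stromal and osteoblast markers 3 fell and 0 rose, with a median log2 difference of -0.61 (camera adjusted p = 0.0198, and adjusted p = 0.322 with an estimated correlation). Cxcl12, a stromal chemokine, fell 2.74-fold from 250 ± 47.4 to 91.1 ± 5.40 CPM, Alpl, alkaline phosphatase, 2.06-fold, and Tnfrsf11b, the RANKL decoy receptor, 2.03-fold. The last pair lost the call under 9 settings for Alpl and 10 for Tnfrsf11b. With all 6 libraries these were limma on log2(FPKM + 1), with log2 differences of -0.93 and -0.86, other limma fits to FPKM, and edgeR on library totals without TMM, with -0.99 and -0.96. Tnfrsf11b also lost it without the filter on low values, at -0.99. Alpl had log2 differences of -0.93 without replicate 2 of day 0 and -0.97 without replicate 3 of day 5, and Tnfrsf11b had -0.88 without replicate 2 of day 0 and -0.97 without replicate 1 of day 5. Collagen transcripts, singled out after their values were seen, were among the most abundant on both days, with Col1a1 at 7438 ± 1786 CPM at day 0 and 4558 ± 350 at day 5. Of 5 tested neutrophil markers 2 rose and 3 fell (camera adjusted p = 0.294), among them S100a9, 6.56-fold higher at 7.87 ± 3.60 CPM on day 5, and Csf3r and Mmp8, 5.82-fold and 4.36-fold lower. Of 3 lymphocyte markers 2 fell, Il7r 2.73-fold and Ighm 2.63-fold (camera adjusted p = 0.169), with log2 differences of -0.81 and -0.93, below the size threshold, in limma on log2(FPKM + 1). Of 3 dendritic cell markers 1 fell, Bst2, which is also an interferon-stimulated gene (camera adjusted p = 0.0343, and adjusted p = 0.233 with an estimated correlation). Both tested erythroid and megakaryocyte markers fell (camera adjusted p = 5.70e-04, and adjusted p = 0.0991 with an estimated correlation). Pf4, a platelet chemokine that macrophages also make, fell 9.13-fold from 153 ± 19.5 to 16.7 ± 0.527 CPM. Hbb-bs, a beta globin with a near-identical copy, had 439 counts at day 0 and 102 at day 5 (adjusted p = 0.0189), and lost the call without replicate 2 of day 0 (log2 -1.63) and without replicate 2 of day 5 (log2 -1.80). With all 6 libraries it also lost the call in DESeq2, robust edgeR, robust limma and edgeR without the filter on low values, with adjusted p from 0.0531 to 0.0921. The 1 tested mast cell and basophil marker, Mcpt8, had a log2 difference of 0.25 ± 0.13 (adjusted p = 0.119).

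Transcripts of epidermis, skeletal muscle and fat also differed by day, in lists chosen after the values were seen. The summed CPM of 11 epidermal keratins was 1.24 ± 0.519 at day 0 and 182 ± 40.9 at day 5, and that of 18 skeletal muscle genes 20.9 ± 3.98 and 78.6 ± 29.7. Acta1, a muscle actin that was not called, made up much of the day 0 muscle sum, with 12.9 ± 1.02 CPM at day 0 and 20.1 ± 4.10 at day 5. The summed CPM of 24 adipocyte markers was 210 ± 15.0 at day 0 and 109 ± 6.01 at day 5. Pnpla2, a lipase that was not called, made up much of both sums, with 74.9 ± 3.41 and 79.1 ± 3.30 CPM, and 16 of the 24 markers were lower without the filter on low values. A few genes had counts on 1 day only. Ucp1, the uncoupling protein of brown fat (chromosome 8, 83290352 to 83298452), had 3016 counts over the 3 day 0 libraries and 0 at day 5, at least 1029-fold lower with a floor of 3 counts over the day. Gm20716, a readthrough gene model that overlaps Adnp and Dpm1 on the same strand (chromosome 2, 168180986 to 168230364), had 10745 counts at day 0 and 0 at day 5, at least 3666-fold lower. Its value is uncertain because the counting could assign shared reads to any of the 3 models, and the CPM summed over them was 122 ± 7.94 at day 0 and 115 ± 3.95 at day 5. The floors cover counting error only.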

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

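The tests with DESeq2, filterByExpr, library totals without TMM and robust edgeR, and the list counts without replicate 1 of day 0, were chosen after the data were seen, and limma on log2(FPKM + 1), planned as the main test, became an alternative then. At the log2 threshold of 1, Vsig4 was called lower under each alternative filter, scaling and test, with log2 differences from -1.34 to -1.08; it lies under a threshold of 2. With 1 library left out, 1446 to 1525 genes were called, and Vsig4 ranged from -1.36 to -1.29. No named gene or list that was called changed direction. The share of called genes that were higher was 47.4% and ranged from 46.0% to 60.4%, so which direction held more calls depended on the setting. The count of 1465 genes (695 higher, 770 lower) moved by over 1.5 times under these settings. Limma on log2(FPKM + 1) called 973 (438 lower), also without trend, 964 when robust (435 lower), and 453 higher after quantile normalization. In the simulated data limma recovered 71 of 100 genes changed by a log2 of 1.5 where edgeR recovered 99. Those counts were drawn with edgeR's own dispersions, so they do not rank the tests on the real libraries. Testing more genes called more, 2303 without a filter (1244 higher) and 2366 with filterByExpr (1234 higher). An FPKM minimum of 5 tested fewer genes and called 839 (400 higher, 439 lower). The adjusted p alone called 6608 (3173 higher, 3435 lower), and a log2 threshold of 2 called 412 (249 higher, 163 lower). DESeq2 called 1460, of which 1440 were among the 1465. Of the 16 fixed lists called by camera, 2 were called with an estimated correlation. Under the other settings camera called 13 to 22 lists, and fry, which compares a list with no change and not with other genes, called 24. Lists not called in the report gained a call in several settings, fry included: ribosomal proteins in 12, RANK signalling in 9, cholesterol synthesis and lymphocyte markers in 7 each, glycolysis in 6, lysosomal proteins in 5, MHC class II presentation in 4, and Nrf2 regulators and neutrophil markers in 1 each. The podosome list lost its call under limma on FPKM and under DESeq2, and the cause was not tested. The lists of inflammatory cytokines and chemokines, dendritic cell markers, and erythroid and megakaryocyte markers each lost the call in 2 settings, the estimated correlation included. Without replicate 1 of day 0, the number of called members of a list changed by at most 2. Same-numbered libraries did not deviate together, with correlations of -0.07, 0.15 and 0.03 across genes, and not every library correlated best with its own number, so the numbers were not taken as pairs. With a replicate block 1470 genes and 16 lists were called, and Vsig4 had a log2 difference of -1.33. The lowest counts limit genes such as Hbb-bs, with 439 counts at day 0 and 102 at day 5.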

Other observations

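Each test in this part was chosen after its result was seen, except the comparison of Vsig4 with genes shared by macrophages and osteoclasts. The adipocyte, epidermal, muscle, shared-lineage and abundant stromal lists were also chosen after the data were seen, and KEGG pathways were taken from the table's own annotation.

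Transcripts of tissues outside the monocyte lineage differed between days. Of 24 adipocyte markers, 16 were lower at day 5 and 0 higher without the filter on low values; with the filter, 9 of 12 tested were lower and 1, Cox7a1, was higher. Pck1, a gluconeogenic enzyme that fat also expresses, went from 14.9 ± 3.08 to 0.183 ± 0.126 CPM. Cidea, a lipid droplet protein, went from 7.68 ± 1.90 to 0.0646 ± 0.0628 CPM, and Fabp4, a fatty acid carrier that macrophages also express, from 43.6 ± 4.71 to 7.30 ± 1.31 CPM. Of 18 skeletal muscle genes, 11 were higher and 0 lower at day 5 without the filter on low values. With the filter, 3 of 5 tested were higher and 0 lower. Among the 11 was Myh1, a myosin heavy chain, at 11.2 ± 6.38 CPM on day 5. All 63 day 0 counts of Myh1 came from replicate 3, as did all 30 of Krt14, and without that library both are at 0 on day 0.

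Among 276 KEGG pathways, camera with the preset correlation called 19 up and 23 down. With an estimated correlation camera called 0, and 11 had an unadjusted p under 0.05. The pathway of oxidative phosphorylation had 36 of 117 genes higher and 1 lower (camera adjusted p = 3.22e-20, and adjusted p = 0.842 with an estimated correlation). How many of these 117 genes are vacuolar ATPase subunits or mitochondrially encoded was not examined, so the 36 are not a count of respiratory chain genes alone. Cytokine-cytokine receptor interaction had 7 of 104 higher and 36 lower (camera adjusted p = 1.93e-04, and adjusted p = 0.842 with an estimated correlation). The KEGG pathway of osteoclast differentiation was not called, unlike the fixed osteoclast list. It had 18 of 110 genes higher and 13 lower, with a median log2 difference of -0.04 (camera adjusted p = 0.419, and adjusted p = 0.921 with an estimated correlation).

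Vsig4 was lower at day 5. A larger share of stromal cells would dilute it, but the fixed stromal and osteoblast list had a median log2 difference of -0.61, which argues against that. Less RNA of the whole lineage would lower genes shared by macrophages and osteoclasts alike. Their median over 20 genes was -0.33 with an SD of 0.71, above the -1.34 of Vsig4 by 1.00, although 6 of the 20 also fell and the lowest reached -1.53. Lower expression with RANKL or with time in culture stays open, untested, since no 5-day culture without RANKL was analysed here, and a smaller share of Vsig4-bearing macrophages may contribute to the same fall.

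Epidermal transcripts were higher at day 5. The summed CPM of 11 keratins was 1.24 ± 0.519 at day 0 and 182 ± 40.9 at day 5, with Krt14 at 43.0 ± 10.1, Krt1 at 28.0 ± 10.6 and Krt10 at 25.2 ± 3.14 CPM on day 5. The 20 epidermal genes outside the keratin family summed to 17.5 ± 1.03 and 89.8 ± 7.24 CPM, and Sbsn, with 2057 counts at day 0, was not called. Reads shared among keratin paralogs would not raise other epidermal genes, and 19 of 20 of those rose without the filter on low values. This argues against that cause for these 19 genes only. The list was chosen after the values were seen, so the share of 19 in 20 is not independent support. Material carried over from another library or tissue and epidermal cells in the cultures cannot be told apart, because the labels record no preparation batch and all 3 day 5 libraries carry the signal. No biological explanation was tested.

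Of the called genes, 21 had a count of 0 in the 3 libraries of 1 day. Of these, 3 (14.3%) overlap a more abundant gene on the same strand, against 2.14% of other tested genes (one-sided Fisher's exact p = 0.00991). These are Gm20716, Gm20521 and Gm49527, and the CPM summed over each locus moved by log2 -0.09, 0.04 and 0.15, so assignment of shared reads to another model is a candidate explanation for them. Another 14, such as Ucp1, Klk7 and Pls1, overlap no gene of the table or of GENCODE M21 on either strand, which argues against it for them. For the 4 that overlap a gene in another way it stays open, since the strand setting of the counting is not known, and no biological explanation was tested. Klk7, Krtdap and Sprr1a among the 14, and Lgals7 and Lypd3 among the 4, are also in the epidermal list above. They are part of that pattern and not a separate one.

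The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 1465 genes, 1 of 10 with as many, and the highest other called 0. For the fixed lists the real split called 16 and the others called from 9 to 16, so 2 of 10 splits gave as many. The other splits mixed the days in unequal numbers, so part of the day difference lay between their groups and part within them. They cannot show how often a gene or list is called without a day difference, and no conclusion is drawn from them. A list call by camera with the preset correlation stays weak evidence taken alone, since 2 of the 16 lists were called with an estimated correlation.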
